A study of Homo sapiens with 30 samples.

How the data were processed

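Gene expression was measured in 3 human carcinoma cell lines on a custom Affymetrix array of 35356 probe sets, with 1 array per RNA sample and 30 arrays in all. RCC4, a renal carcinoma line, took 20 arrays, as VHL-null cells and as cells into which wild-type VHL had been put back, called VHL-restored here. H1299, a lung carcinoma line, took 4 arrays and HCT116, a colon carcinoma line, took 6, each as p53-null and p53 wild-type cells. Hypoxia meant oxygen below 0.01% in an anoxic incubator. The authors ran independent replicates only for RCC4 at 0 h and 18 h, 2 per genotype, so every other group is a single array.

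The values are deposited as linear intensity, in whole numbers, scaled by the authors with a method that the labels do not state, and the labels do not say what a null entry stands for. Null entries fell on probe sets that were dim on the other arrays, and they made up between 18.4% and 40.4% of the probe sets of an array. The arrays fall into 2 sets by 5 control entries that are blank on 18 arrays (set 1) and filled on 12 (set 2). Set 1 holds replicate 1 of RCC4 at 0 h and 18 h, the RCC4 arrays at 2 h and 6 h, and all H1299 and HCT116 arrays. Set 2 holds replicate 2 of RCC4 at 0 h and 18 h, the arrays at 1 h and 4 h, and both reoxygenation times. The median listed intensity per array was 145 to 174 in set 1 and 201 to 222 in set 2. For arrays, the precision is limited by their number.

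Null entries were taken as 0, and values were analysed as log2(value + 16). Array medians of the genes spanned 0.903 on the log2 scale, above the limit of 0.2 set for leaving arrays as they were, so each array was centred on its median, and every change is relative to that median. Of 17478 annotated probe sets, 16905 carried a single symbol, and the brightest probe set of each gene gave 12690 genes. The upper 60% by mean value, 7614 genes, were tested. CA9 and SLC2A1 were not among the annotated single-symbol genes and are not analysed here, while VHL, VEGFA and EGLN3 were too dim for the tested genes and are given at most as intensities per array.

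Tests used limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 7614 genes (the adjusted p, or padj) and a threshold of 0.05. The 8 replicated RCC4 arrays were fitted with a mean per group, with contrasts for hypoxia in each genotype, for VHL at 0 h and 18 h, and for the interaction. All 20 RCC4 arrays were fitted with terms for genotype and state, which tests only a change shared by both genotypes. H1299 and HCT116 were fitted with line and genotype as a block for 24 h hypoxia, and with line and time as a block for p53. The p53 effect was also fitted in HCT116 alone, the p53 by hypoxia interaction was fitted in both lines, and late hypoxia was fitted over 6 backgrounds (lines and genotypes) after averaging replicates. P-values measure only the spread between these samples, and where genotypes of a line or times serve as replicates they measure repeatability over those, not over independent clones.

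Whether replicate numbers pair the RCC4 samples was checked by correlating replicate differences between groups across genes, which are not independent replicates. The correlations were 0.794 to 0.916 over 6 pairs of groups, so the replicate number marks a difference shared by the groups. Results with the replicate number as a block stand beside those without it. At 0 h and 18 h the replicate number equals the array set. A difference between the sets could give these correlations, so the check cannot show that the numbers pair independent experiments. In the fit of all 20 RCC4 arrays the replicate number does not follow the set, so the array set was used as the block there.

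Gene lists and named genes followed rules fixed before the data were examined, as were the comparisons, the tests and most alternatives. The 19 lists hold HIF targets outside glycolysis, glycolysis, p53 targets, ATF4 stress genes, endoplasmic reticulum chaperones, heat shock genes, G2/M genes, S phase genes, DNA repair, NF-kB and inflammation, interferon response, immediate early genes, lipid and cholesterol synthesis, oxidative phosphorylation, ribosome biogenesis, splicing, matrix and mesenchymal genes, NRF2 targets and metallothioneins. Another 5 lists hold markers of renal, colon, leukocyte, endothelial and fibroblast cells, which were given per array without a test. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 19 lists of a comparison. Of 304 such list results, 110 were called with the preset correlation and 10 with the estimated correlation. The median, the mean and the test of a list differed in sign in 46 of the 304, of which 1 was called.

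The named genes are, for each comparison, the 10 with the largest rise and the 10 with the largest fall among genes that passed the test and moved the same way in every pairing, up to 4 members per list by the size of limma's statistic, and 9 genes named throughout. A value on every array of the fit was also required of the largest changes, the rule was applied to the fit with the block as well as without, and members of lists were ranked in the fit without it. Each RCC4 gene reported as passing a test moved the same way in both pairs of arrays.

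The alternatives were pseudocounts of 1 and 64, quantile normalisation, no centring, no filter or the upper 30%, the mean of a gene's probe sets, a variance trend, a replicate block, a fit on all 20 RCC4 arrays for the replicated contrasts, and leaving out each replicate or pair. Chosen after seeing the data were leaving out null entries, the array set as a block, fits within an array set, and leaving out the arrays at 1 h and 4 h or arrays of H1299. The tests of explanations, the splits of the samples included, were all set after the results were seen.

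The fits were tested on simulated data of 7614 genes with 100 planted changes per size and noise independent between genes. Of changes of 1 on the log2 scale, 58% were recovered for hypoxia in VHL-null cells without a block and 100% with the replicate block, and 7% for the VHL by hypoxia interaction without a block and 100% with it. For 24 h hypoxia in H1299 and HCT116 95% were recovered, and for p53 in HCT116 100%, with 10 and 15 unchanged genes called beside them. The changed genes were drawn at random from all those tested. These shares therefore do not hold for genes with a wide spread, such as ADM in 24 h hypoxia (SE 0.708). Preparation and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.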

Results

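Expression was followed in RCC4 cells without and with VHL at 0, 1, 2, 4, 6 and 18 h of hypoxia and at 1 h and 4 h of reoxygenation after 18 h. H1299 cells without and with wild-type p53 were measured at 0 h and 24 h, and HCT116 cells of both p53 genotypes at 0, 12 and 24 h. The 4 RCC4 groups at 0 h and 18 h held 2 arrays each, and every other group held 1. Array intensities reached 3577 to 5055 at their highest.

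VHL itself, the ubiquitin ligase component that marks HIF proteins for degradation in oxygen, was dim and was not tested. At 0 h its intensity was 20 and 109 on the VHL-null arrays and 26 and 40 on the VHL-restored arrays, and at 18 h it was 14 and 76 against 11 and 2. Which part of the transcript the probes read is not stated, so these values do not check the genotype. VEGFA, the angiogenic growth factor, had intensities of 112 and 163 on the VHL-null arrays at 0 h and was null on both VHL-restored arrays, where it was listed at 49 and 41 after 18 h. EGLN3, a HIF prolyl hydroxylase, was listed on the VHL-null RCC4 arrays, at 48 and 242 at 0 h, and was null on every VHL-restored array. CA9 and SLC2A1 are not analysed here. Of the cell type markers, 1 to 3 of 6 renal genes lay above the array median in RCC4, 2 in H1299 and 1 to 2 in HCT116. Of 8 colon genes, 1 to 2 did in HCT116 and 1 in RCC4 and in H1299, so by these counts the renal and colon lists do not tell the lines apart. For endothelial markers it was 3 to 6 of 8 in RCC4, 4 to 5 in H1299 and 5 to 6 in HCT116. For fibroblast markers it was 1 to 3 of 9 in RCC4, and for leukocyte markers 1 to 3 of 9.

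The first comparison asks how the VHL genotypes differ in oxygen, with VHL-null against VHL-restored RCC4 at 0 h (n = 2 each). The labels name no separate clones of either genotype. Here and at 18 h, other differences between the VHL-null and VHL-restored cells cannot be told apart from VHL loss. SYT13, a synaptotagmin, was 18.1-fold higher in VHL-null cells (log2 difference 4.18, SE 0.190, limma adjusted p = 0.00022). Hypoxia genes were already high in oxygen without VHL: CA12, a membrane carbonic anhydrase, was 5.64-fold higher (adjusted p = 0.0346), BNIP3, a mitophagy receptor, 4.73-fold (0.0438), and ADM, the vasodilator adrenomedullin, 4.63-fold (0.0159). ENO2, a glycolytic enolase, was 3.31-fold higher (0.0424) and the G1 cyclin gene CCND1 was 3.41-fold higher (0.0346), as were NRN1 at 5.52-fold (0.0438) and TRIB3, a stress-induced pseudokinase, at 2.84-fold (0.0346). CCND2, another G1 cyclin, went the other way, with a log2 difference of -3.18 (SE 0.368, adjusted p = 0.0381). In all, limma called 9 genes, 8 higher and 1 lower.

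With the replicate number as a block, 572 genes differed, 236 higher and 336 lower in VHL-null cells, and they held all 9. Among them were F3, tissue factor, with a log2 difference of 2.50 (SE 0.228, adjusted p = 1.68e-06), and COXFA4L2, a mitochondrial HIF target also known as NDUFA4L2, at 2.00 (SE 0.182, padj = 1.68e-06). SCD, the stearoyl-CoA desaturase, stood at 1.62 (SE 0.115, padj = 9.15e-08). NDRG1, a hypoxia-responsive gene, differed by 1.49 (SE 0.163, padj = 1.38e-05), though its adjusted p was 0.148 without the block. Single genes were lower in VHL-null cells, such as FN1, fibronectin, by log2 -2.08 (SE 0.127, padj = 1.55e-08), C3 by -2.30 (SE 0.312, padj = 0.000136), C1S by -2.56 (SE 0.344, padj = 0.000128) and CCN2, connective tissue growth factor, by -2.16 (SE 0.370, padj = 0.00117). KRT18, a simple epithelial keratin, was lower by -1.55 (SE 0.137, padj = 1.3e-06) and ABCB1, a drug efflux pump, by -1.37 (SE 0.118, padj = 9.97e-07).

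As a list, 21 of 26 HIF targets were higher in VHL-null cells (median log2 difference 0.74, camera adjusted p = 1.61e-23). Of these, 4 passed the gene test and 13 passed adjusted over the list alone, with 2 others lower, and with the block 16 were higher and 2 lower. Glycolysis genes were higher too, 15 of 17 (median 0.31, padj = 1.34e-12, 8 higher with the block and 9 adjusted over the list alone). PDK1, which restrains pyruvate oxidation, was at 1.12 (SE 0.117, blocked padj = 7.9e-06), and HK1 at 0.89 (SE 0.108, blocked padj = 4.82e-05). All 15 genes of lipid and cholesterol synthesis were higher (median 0.23, padj = 8.97e-10), with 6 called under the block. INSIG1 was at 0.92 (SE 0.135, blocked padj = 0.000274) and FADS2 at 0.76 (SE 0.115, blocked padj = 0.000395). With an estimated correlation the adjusted p was 0.0826 for HIF targets, 0.299 for glycolysis and 0.0826 for lipid synthesis. By replicate, the glycolysis median was 0.50 and 0.14. The matrix and mesenchymal list was not called (padj = 0.674), and its median was 0.03 against a mean of -0.12. Without the block, leaving out replicate 1 of VHL-restored at 0 h or either VHL-null array at 0 h left 1 gene.

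Hypoxia for 18 h in VHL-restored RCC4 cells, into which wild-type VHL had been put back, gives the response of these cells to anoxia (n = 2 arrays per time). ADM rose 6.98-fold (log2 2.80, SE 0.195, limma adjusted p = 0.00545), ENO2 4.45-fold (log2 2.15, SE 0.207, padj = 0.0204) and TRIB3 3.57-fold (log2 1.83, SE 0.167, padj = 0.0200), and no others were called without a block. With the replicate number as a block 501 genes changed, 282 up and 219 down. PPP1R3C, which targets a phosphatase to glycogen, rose by log2 2.63 (SE 0.150, padj = 9.62e-09), BNIP3 by 2.38 (SE 0.159, padj = 5.26e-08), NDRG1 by 1.86 (SE 0.163, padj = 1.84e-06), the growth factor gene TGFA by 1.83 (SE 0.158, padj = 1.48e-06) and EDN1, endothelin-1, by 1.81 (SE 0.105, padj = 9.74e-09). Without the block their adjusted p lay at 0.0522 for PPP1R3C and BNIP3, 0.0549 for TGFA and EDN1, and 0.0790 for NDRG1.

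All 26 HIF targets had positive changes (median 0.81, camera adjusted p = 1.59e-48, 0.0262 with an estimated correlation), of which 1 passed the gene test, 16 passed adjusted over the list alone, and 19 passed under the block. Under the block the list's adjusted p with an estimated correlation was 0.184. Glycolysis genes rose (16 of 17, median 0.49, padj = 1.70e-19), with 11 called under the block. PDK1 was at 1.53 (SE 0.117, blocked padj = 3.49e-07), PFKFB4, a regulator of glycolytic flux, at 1.37 (SE 0.110, blocked padj = 5.94e-07) and glycogen synthase GYS1 at 1.32 (SE 0.121, blocked padj = 2.82e-06). ATF4 stress genes rose (16 of 19, median 0.34, padj = 1.44e-11), with 7 called under the block. STC2 was at 1.64 (SE 0.146, blocked padj = 2.22e-06), ATF3 at 1.58 (SE 0.169, blocked padj = 1.5e-05) and DDIT4, an inhibitor of mTORC1, at 1.31 (SE 0.126, blocked padj = 4.41e-06). The adjusted p with an estimated correlation was 0.0755 for glycolysis and 0.0547 for ATF4 genes.

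Cell division genes fell in the same cells: 0 of 18 G2/M genes had a positive change (median -0.37, camera adjusted p = 1.70e-19), and 10 fell under the block, 13 adjusted over the list alone. Their median was -0.54 in replicate 1, with 0 of 18 higher, and -0.22 in replicate 2, with 2 of 18. KPNA2, a nuclear importin, was at log2 -1.24 (SE 0.113, blocked padj = 2.5e-06), PLK1, a mitotic kinase, at -0.96 (SE 0.120, blocked padj = 8.18e-05), KIF20A at -0.84 (SE 0.117, blocked padj = 0.000201) and CCNB1, cyclin B1, at -0.80 (SE 0.104, blocked padj = 0.000104). Heat shock genes fell as well (1 of 12 positive, median -0.29, padj = 3.24e-11, 5 called under the block). HSPH1 was at -1.07 (SE 0.121, blocked padj = 2.94e-05) and HSPE1 at -0.96 (SE 0.0981, blocked padj = 8.56e-06). Endoplasmic reticulum chaperones had a median of 0.23 (12 of 13, padj = 0.00416, 4 called under the block), but it was 0.07 in replicate 1, with 7 of 13 higher, and 0.63 in replicate 2, with 13 of 13. Among them were HERPUD1 at 0.97 (SE 0.106, blocked padj = 1.9e-05) and HSPA5 at 0.56 (SE 0.110, blocked padj = 0.00463). With an estimated correlation the adjusted p was 0.0547 for G2/M and heat shock genes and 0.311 for chaperones.

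Targets of p53 rose with hypoxia there (21 of 24, median 0.20, camera adjusted p = 5.98e-06, 5 called under the block and 8 adjusted over the list alone). DDB2, a DNA damage recognition gene, was at 1.21 (SE 0.0951, blocked padj = 4.48e-07) and the cell cycle inhibitor CDKN1A at 0.71 (SE 0.131, blocked padj = 0.00277). MDM2, which encodes the ligase that degrades p53, had a change of 0.16 (SE 0.103, blocked padj = 0.515). NF-kB genes rose (12 of 13, median 0.29, padj = 0.000112), such as TNFAIP3 at 1.67 (SE 0.172, blocked padj = 8.64e-06) and ICAM1 at 1.08 (SE 0.126, blocked padj = 4.16e-05). Ribosome biogenesis genes fell (median -0.05, padj = 0.00662), with 3 called under the block, and splicing genes fell (median -0.15, padj = 0.0125) with 0 called by limma. The estimated correlation gave an adjusted p of 0.107 for p53 targets, 0.0755 for NF-kB, 0.145 for ribosome biogenesis and 0.474 for splicing. Without the block, leaving out either VHL-restored 18 h array or replicate 1 at 0 h left 0 genes.

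In VHL-null RCC4 cells, hypoxia for 18 h asks what response is left when VHL is missing (n = 2 per time), and limma called 0 genes without a block (51 at an unadjusted p under 0.05, smallest adjusted p 1). With the replicate number as a block 37 genes changed, 21 up and 16 down. CDKN1A rose by log2 1.21 (SE 0.131, adjusted p = 0.000226), DDB2 by 0.95 (SE 0.0951, padj = 0.000179), ATF3 by 1.42 (SE 0.169, padj = 0.000392) and GDF15, a stress cytokine, by 1.03 (SE 0.168, padj = 0.00741). TSC22D3, a glucocorticoid-induced gene, rose by 0.94 (SE 0.121, padj = 0.00079), EFNA1 by 0.94 (SE 0.166, padj = 0.0147), RASSF4 by 0.77 (SE 0.117, padj = 0.00344) and JUNB by 0.67 (SE 0.0990, padj = 0.00316). PLK1 fell by 1.09 (SE 0.120, padj = 0.000226), DEPDC1 by 1.02 (SE 0.132, padj = 0.00079) and KPNA2 by 0.96 (SE 0.113, padj = 0.000382). The centromere protector SGO2 fell by 0.89 (SE 0.117, padj = 0.000911), CCNB1 by 0.69 (SE 0.104, padj = 0.00344) and TOP2A, a topoisomerase of dividing cells, by 0.68 (SE 0.120, padj = 0.0147).

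The lists moved in VHL-null cells with these genes. G2/M genes fell (3 of 18 positive, median -0.35, camera adjusted p = 5.01e-22), with 4 called under the block and 11 adjusted over the list alone. Targets of p53 rose (23 of 24, median 0.23, padj = 3.49e-16), with 3 called under the block and 10 adjusted over the list alone, while MDM2 stood at 0.12 (SE 0.103, blocked padj = 0.887). HIF targets rose by less than in the restored cells (24 of 26, median 0.18, padj = 3.02e-11), with 5 called under the block. HILPDA, a lipid droplet protein gene, was at 0.69 (SE 0.138, blocked padj = 0.0374) and ADM at 0.61 (SE 0.127, blocked padj = 0.0460), whereas NDRG1 had 0.40 (SE 0.163, blocked padj = 0.461). The difference between the genotypes is tested by the interaction. ATF4 genes rose (18 of 19, median 0.31, padj = 3.40e-11), with DDIT4 at 0.62 (SE 0.126, blocked padj = 0.0426) and TRIB3 at 0.54 (SE 0.107, blocked padj = 0.0338), and so did NF-kB genes (13 of 13, median 0.13, padj = 0.000215), with NFKBIA at 0.54 (SE 0.0986, blocked padj = 0.0182). The estimated correlation gave an adjusted p of 0.0726 for G2/M, p53 and ATF4 genes and 0.0940 for HIF targets and NF-kB genes. Interferon genes had a median of 0.13 (10 of 12, padj = 0.0136, 0.422 with an estimated correlation). By replicate, the median was 0.04 and 0.18 for interferon genes and 0.01 and 0.30 for NF-kB genes, so both rest mainly on replicate 2. It was larger in replicate 2 also for p53 targets, 0.12 (19 of 24 higher) and 0.30 (22 of 24), and for HIF targets, 0.10 (19 of 26) and 0.24 (26 of 26).

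The VHL by hypoxia interaction asks whether the 18 h change differed between the genotypes. Without a block limma called 0 genes (45 at an unadjusted p under 0.05, smallest adjusted p 0.404, that of ADM), and with the replicate number as a block it called 43, 5 positive and 38 negative. The difference of log2 changes was -2.27 for BNIP3 (SE 0.225, padj = 2.58e-05), -2.20 for ADM (SE 0.180, padj = 3.18e-06), -2.00 for PPP1R3C (SE 0.212, padj = 5.76e-05), -1.92 for NRN1 (SE 0.145, padj = 2.51e-06) and -1.84 for ENO2 (SE 0.144, padj = 2.51e-06). UFSP2, a protease gene, followed with -1.81 (SE 0.175, padj = 2.22e-05) and F3 with -1.72 (SE 0.322, padj = 0.0185). EDN1 stood at -1.61 (SE 0.149, padj = 1.42e-05), NDRG1 at -1.45 (SE 0.231, padj = 0.00533), PDK1 at -1.38 (SE 0.166, padj = 0.000232), TRIB3 at -1.29 (SE 0.152, padj = 0.000208) and SCD at -1.08 (SE 0.163, padj = 0.00336). Among the 5 positive were HSPE1, a mitochondrial chaperonin gene, at 0.74 (SE 0.139, padj = 0.0185), MRPL15 at 0.68 (SE 0.141, padj = 0.0377) and TNFSF9 at 1.20 (SE 0.229, padj = 0.0202).

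As lists, HIF targets had the largest median difference of the 19 in size, -0.63 (2 of 26 positive, camera adjusted p = 2.08e-51, 0.0234 with an estimated correlation), with 11 called under the block and 19 adjusted over the list alone. Under the block the list's adjusted p with an estimated correlation was 0.246. Within the array sets the median was -0.874 in set 1 and -0.504 in set 2. Glycolysis genes also had a lower change without VHL (3 of 17 positive, median -0.30, padj = 1.07e-17) and heat shock genes a higher change (11 of 12 positive, median 0.30, padj = 1.93e-05), each with an adjusted p of 0.249 with an estimated correlation. Targets of p53 showed no called difference (median 0.04, padj = 0.0693).

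**Figure D1:**
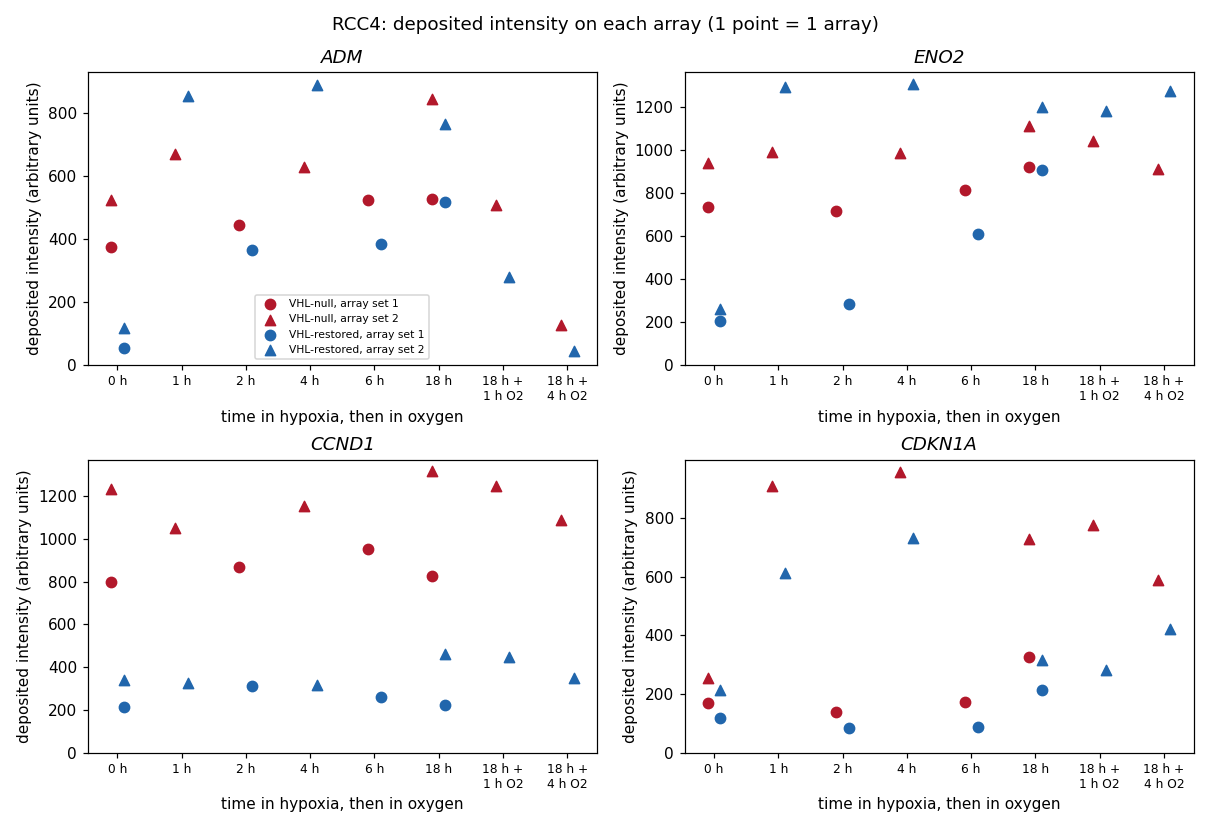
Deposited intensity (arbitrary units) of ADM, ENO2, CCND1 and CDKN1A on each of the 20 RCC4 arrays by time in hypoxia and then in oxygen, with genotype as colour and array set as marker, 1 point per array. ADM stood at 53 and 116 on the VHL-restored arrays at 0 h and at 375 and 524 on the VHL-null arrays.

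The VHL genotypes were compared again after 18 h of hypoxia (n = 2 arrays each). SYT13 was 11.1-fold higher in VHL-null cells (log2 3.47, SE 0.190, limma adjusted p = 0.000895) and RASSF4 3.39-fold (log2 1.76, SE 0.179, padj = 0.0440), the 2 genes called without a block. With the replicate number as a block 578 genes differed, 276 higher and 302 lower. CCND1 was higher by 1.58 (SE 0.122, padj = 4.62e-07), CA12 by 1.44 (SE 0.0973, padj = 1.21e-07) and CDKN1A by 0.81 (SE 0.131, padj = 0.000792). CCND2 differed by -3.32 (SE 0.226, padj = 1.21e-07, 0.0557 without the block), C3 by -2.40 (SE 0.312, padj = 0.00011), FN1 by -1.93 (SE 0.127, padj = 1.21e-07), PHLDA1 by -1.57 (SE 0.112, padj = 1.75e-07) and CITED2, a competitor of HIF for its coactivator, by -1.04 (SE 0.0990, padj = 3.85e-06). NDRG1 differed by 0.04 (SE 0.163, blocked padj = 0.933).

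HIF targets as a list were not called at 18 h (median -0.06, camera adjusted p = 0.519), nor was glycolysis (padj = 0.907). Lipid and cholesterol synthesis genes were higher in VHL-null cells (12 of 15, median 0.34, padj = 2.92e-13), with 8 called under the block and 10 adjusted over the list alone. FADS2 was at 1.15 (SE 0.115, blocked padj = 7.14e-06), FADS1 at 0.91 (SE 0.103, blocked padj = 2.58e-05) and DHCR7 at 0.81 (SE 0.0985, blocked padj = 4.81e-05). S phase genes were higher (17 of 20, median 0.21, padj = 3.41e-07, 7 under the block). RRM2 was at 0.88 (SE 0.186, blocked padj = 0.00669), RFC5 at 0.87 (SE 0.136, blocked padj = 0.00061) and PCNA at 0.72 (SE 0.114, blocked padj = 0.000652). Endoplasmic reticulum chaperones were lower (1 of 13 positive, median -0.33, padj = 0.00076, 5 under the block). HSPA5 was at -0.83 (SE 0.110, blocked padj = 0.000128), the transcription factor XBP1 at -0.82 (SE 0.115, blocked padj = 0.000225) and HERPUD1 at -0.77 (SE 0.106, blocked padj = 0.000195). NF-kB genes were lower (3 of 13 positive, median -0.10, padj = 0.00913), with ICAM1 at -1.02 (SE 0.126, blocked padj = 6.33e-05). With an estimated correlation the adjusted p was 0.0864 for lipid synthesis, 0.336 for S phase and NF-kB genes and 0.444 for chaperones. Leaving out single arrays without the block left 1 or 2 genes.

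The time course holds 1 array per genotype at each further time, so the tests cover only changes shared by both genotypes (2 arrays against the 4 at 0 h). On the arrays labelled 1 h, p53 targets and stress genes were up and mitotic genes down. ATF3 rose by log2 2.74 (SE 0.392, limma adjusted p = 0.00382), TNFAIP3 by 2.31 (SE 0.420, padj = 0.0141) and PPP1R3C by 2.23 (SE 0.447, padj = 0.0242). CDKN1A rose by 1.84 (SE 0.193, padj = 0.000138), DDB2 2.83-fold (log2 SE 0.144, padj = 0.000113), HILPDA by 1.41 (SE 0.290, padj = 0.0287), TGFA by 1.36 (SE 0.258, padj = 0.0168) and TSC22D3 by 1.35 (SE 0.140, padj = 0.000138). PLK1 fell by 2.21 (SE 0.389, padj = 0.0115), and CCNB1 and KPNA2 each fell by 1.10 (SE 0.234, padj = 0.0306, and SE 0.193, padj = 0.0115). MDM2 stood at 0.58 (SE 0.152, padj = 0.0757) and passed with the array set as a block (0.70, SE 0.134, padj = 0.0110). In all 104 genes changed, 76 up and 28 down, against 275 with the array set as a block and 186 within set 2 alone. Leaving out replicate 1 of VHL-restored at 0 h left 38, and without centring 0 genes were called.

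The arrays labelled 4 h gave the largest count of the time course, 451 genes, 332 up and 119 down, against 810 with the array set as a block and 721 within set 2 alone. DDB2 rose by 1.82 (SE 0.144, limma adjusted p = 7.37e-06), CDKN1A by 1.97 (SE 0.193, padj = 5.14e-05), ATF3 by 2.98 (SE 0.392, padj = 0.00113), TNFAIP3 by 2.36 (SE 0.420, padj = 0.00590). SDF2L1, a chaperone partner of the endoplasmic reticulum, rose by 1.94 (SE 0.371, padj = 0.00821), ADM by 1.73 (SE 0.457, padj = 0.0363) and MDM2 by 0.70 (SE 0.152, padj = 0.0151). PLK1 fell by 2.06 (SE 0.389, padj = 0.00801), the claudin gene CLDN2 by 2.16 (SE 0.362, padj = 0.00414), KIF20A by 1.23 (SE 0.193, padj = 0.00272) and HSPE1 by 0.90 (SE 0.258, padj = 0.0496). Leaving out replicate 1 of VHL-restored at 0 h left 202 genes, and without centring 12 were called.

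Lists called at both times included p53 targets, with 23 of 24 positive at 1 h (median 0.62, camera adjusted p = 8.95e-20, 0.00178 with an estimated correlation) and 24 of 24 at 4 h (median 0.73, padj = 2.11e-18, 0.00243 with an estimated correlation). Of them 9 passed the gene test at 1 h and 18 adjusted over the list alone, and at 4 h it was 15 and 19. ATF4 genes rose at 1 h (median 0.86, padj = 6.41e-13, 0.00897 with an estimated correlation) and at 4 h (median 0.87, padj = 1.69e-09, 0.0296 estimated), though the estimated p at 4 h was 0.0847 with the array set as a block. Endoplasmic reticulum chaperones rose (median 0.90 at 1 h, padj = 9.75e-09, and 1.15 at 4 h, padj = 8.66e-10), but their adjusted p with an estimated correlation was 0.0573 and 0.0633. G2/M genes fell (median -0.44 at 1 h, padj = 3.00e-10, and -0.42 at 4 h, padj = 5.69e-08), with estimated-correlation adjusted p of 0.0463 and 0.0948. HIF targets rose at 1 h (25 of 26, median 0.81, padj = 2.39e-14) and 4 h (25 of 26, median 0.80, padj = 1.28e-10), with estimated-correlation adjusted p of 0.0573 and 0.124. NF-kB genes rose at 1 h (median 0.44, padj = 3.28e-07, 0.00937 with an estimated correlation) and so did immediate early genes (median 0.52, padj = 1.95e-06, 0.0359), but with the array set as a block these estimated p were 0.0540 and 0.193. At 4 h NF-kB genes rose too (12 of 13, median 0.44, padj = 4.23e-05, 0.0351 with an estimated correlation, 0.146 with the array set as a block). Metallothionein genes had a median of -0.28 at 4 h (0 of 6 positive, padj = 0.0174, 0.528 with an estimated correlation), but within set 2 it was -0.23 in VHL-null and -0.003 in VHL-restored cells, with 1 of 6 and 2 of 6 higher. These medians compare arrays of set 2 with 0 h arrays of both sets. Within set 2 the medians of ATF4 genes were smaller, 0.42 in VHL-null and 0.61 in VHL-restored cells at 1 h and 0.58 and 0.71 at 4 h. Those of chaperones were 0.47 and 0.86 at 1 h and 0.64 and 0.97 at 4 h.

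At 2 h limma called 2 genes, both down: CDK19, a Mediator kinase, fell by 0.74 (SE 0.115, adjusted p = 0.0318) and the tankyrase gene TNKS fell by 0.65 (SE 0.0984, padj = 0.0318). With the array set as a block 11 genes fell, among them HSD17B11 at -0.83 (SE 0.107, padj = 0.00354, 0.471 without it), and 4 were called within set 1 alone. Without the block, leaving out single arrays gave 0 to 12 genes, 0 without replicate 1 of VHL-restored at 0 h and 12 without replicate 1 of VHL-null at 0 h, and without centring 0 were called. At 6 h it called 0 genes (254 at an unadjusted p under 0.05), and 0 with the array set as a block. G2/M genes fell at 2 h (median -0.30, camera adjusted p = 9.91e-11) and 6 h (median -0.29, padj = 1.24e-10), and HIF targets rose at 6 h (26 of 26, median 0.28, padj = 0.000186), with estimated-correlation adjusted p of 0.172, 0.176 and 0.556. Glycolysis genes had a median of 0.22 at 6 h (17 of 17 positive, padj = 0.0331), which was not called with an estimated correlation (padj = 0.616) or with the array set as a block (padj = 0.281). By genotype within set 1, the 6 h median of glycolysis was -0.003 in VHL-null cells, with 8 of 17 higher, and 0.18 in VHL-restored cells, with 15 of 17. The G2/M median was -0.12 in VHL-null and -0.38 in VHL-restored cells at 2 h, and -0.05 and -0.44 at 6 h.

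By genotype and within an array set, the median change of HIF targets in VHL-restored cells was 0.19 at 2 h, 0.57 at 6 h and 0.95 at 18 h in set 1, and 0.80 at 1 h, 0.85 at 4 h and 0.78 at 18 h in set 2. In VHL-null cells it was -0.01, 0.07 and 0.10 in set 1 and 0.38, 0.40 and 0.24 in set 2. The median of p53 targets was -0.03 at 2 h and 0.68 at 1 h in VHL-null cells, and -0.04 and 0.45 in VHL-restored cells. These are single arrays without a test, and the times are split between the array sets.

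Reoxygenation asks how expression moves when oxygen returns after 18 h. At 4 h of oxygen the largest changes were falls: PLK2, a stress-induced polo-like kinase, fell by log2 3.45 (SE 0.502, limma adjusted p = 0.00237), ADM by 2.89 (SE 0.457, padj = 0.00512), the amino acid transporter gene SLC38A2 by 2.33 (SE 0.392, padj = 0.00788), FBXO5 by 2.09 (SE 0.418, padj = 0.0214), PHLDA1 by 1.90 (SE 0.243, padj = 0.00126), the MYC antagonist MNT by 1.82 (SE 0.350, padj = 0.0178) and NFKBIA by 1.73 (SE 0.244, padj = 0.00212). Fewer rose, such as the nucleoporin gene NUP58 by 1.10 (SE 0.216, padj = 0.0200), RNF6 by 1.05 (SE 0.234, padj = 0.0473), ODR4 by 0.85 (SE 0.153, padj = 0.0120) and PSIP1 by 0.67 (SE 0.119, padj = 0.0116). The count was 61 genes, 10 up and 51 down, and 200 with the array set as a block, 72 up and 128 down, with IER5 at -1.80 (SE 0.333, padj = 0.00802, 0.196 without it). Leaving out replicate 2 of VHL-restored at 18 h gave 149, and without centring 4 were called. By genotype, PLK2 changed by -5.30 in VHL-restored and -2.16 in VHL-null cells, SLC38A2 by -3.83 and -1.07, and ADM by -3.41 and -2.42, and this difference was not tested. Within set 2, 102 genes were lower by more than 1 on the log2 scale and 0 higher in VHL-restored cells, and 29 and 0 in VHL-null cells. The changes tested by limma compare arrays of set 2 with 18 h arrays of both sets. The rises above 1 of NUP58 and RNF6 therefore did not reach that size within set 2.

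Immediate early genes fell at 4 h of oxygen (0 of 17 positive, median -0.22, camera adjusted p = 0.00215, 0.308 with an estimated correlation), and splicing genes rose (11 of 11, median 0.28, padj = 1.24e-05, 0.308 estimated). DNA repair genes had a median of 0.28 (padj = 0.00984, 0.168 estimated), which was not called with the array set as a block (padj = 0.289). Within set 2, in VHL-null and VHL-restored cells, DNA repair stood at 0.06 and 0.13, splicing genes at 0.09 and 0.14, and immediate early genes at -0.20 (1 of 17 higher) and -0.54 (5 of 17). HIF targets were not called (median 0.01, mean -0.19, padj = 0.434). Within set 2 their median was -0.07 in VHL-null cells, with 9 of 26 higher, and 0.22 in VHL-restored cells, with 18 of 26, single pairs without a test. At 1 h of oxygen limma called 0 genes (633 at an unadjusted p under 0.05), and 0 with the array set as a block. There camera called 8 of 19 lists, all up, and 0 with an estimated correlation. Among the 8 were chaperones (median 0.39, padj = 0.000753), heat shock genes (median 0.24, padj = 0.00579), splicing genes (median 0.26, padj = 1.91e-05), oxidative phosphorylation (median 0.14, padj = 0.000221) and NRF2 targets (median 0.17, padj = 0.00959). The other 3 were p53 targets (median 0.09, padj = 0.0165), S phase genes (median 0.10, padj = 0.00959) and DNA repair (median 0.13, padj = 0.0232). With the array set as a block the adjusted p of the 8 lay between 0.0730 and 0.557. These medians compare arrays of set 2 with 18 h arrays of both sets, and within set 2 they were smaller. In VHL-null and VHL-restored cells they were 0.11 and 0.01 for chaperones, 0.06 and 0.06 for heat shock genes, 0.06 and 0.10 for splicing genes, and 0.02 and 0.03 for oxidative phosphorylation. NRF2 targets stood at 0.03 and 0.08, S phase genes at 0.02 and 0.03, and DNA repair at 0.03 and 0.06. Targets of p53 went opposite ways, at 0.13 (20 of 24 higher) and -0.05 (8 of 24).

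Hypoxia for 24 h in H1299 and HCT116 asks which changes are shared by 4 backgrounds with 1 pair of arrays each. In 3 of them hypoxia genes were higher at 24 h: BNIP3 changed by log2 3.79 in p53-null H1299, 2.80 in p53-null HCT116 and 3.08 in p53 wild-type HCT116, and NDRG1 by 1.04, 1.11 and 1.69. The H1299 p53 wild-type pair went the other way, with BNIP3 at -3.37, NDRG1 at -0.80, the chaperone gene HSPA5 at -1.99 and CCNB1 at 1.36. HSPA5 was at 1.84 in p53-null H1299, and CCNB1 at -1.54 there and at -1.69 and -3.06 in p53-null and wild-type HCT116. For the change shared by the 4, limma called 0 genes (427 at an unadjusted p under 0.05), with the p53 target PERP at 0.51 (SE 0.0958, adjusted p = 0.653) and the actin gene ACTA2 at 0.57 (SE 0.136, padj = 0.653). Leaving out the H1299 p53 wild-type pair gave 7 genes.

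As lists over these 4 backgrounds, p53 targets rose (21 of 24, median 0.21, camera adjusted p = 4.89e-05), G2/M genes fell (1 of 18 positive, median -0.30, padj = 0.000113), and glycolysis (16 of 17, median 0.49) and HIF targets (23 of 26, median 0.24) rose (both padj = 0.00156), all with an adjusted p of 0.663 with an estimated correlation. These are averages, and in the H1299 p53 wild-type pair 18 of 18 G2/M genes were higher (median 0.52), while 1 of 17 glycolysis genes (median -0.61) and 7 of 26 HIF targets (median -0.43) were. Targets of p53 stood at 0.04 in p53-null HCT116, with 14 of 24 higher, and at 0.16 in p53 wild-type HCT116, with 16 of 24. In H1299 they stood higher in p53-null cells, at 0.30 with 22 of 24, than in the wild-type pair, at 0.22 with 20 of 24. Adjusted over the list alone, 0 members were called by limma. Over the 6 backgrounds of all 3 lines limma called 0 genes (925 at an unadjusted p under 0.05), with ADM at 1.66 (SE 0.545, adjusted p = 0.395), IER3 at 0.34 (SE 0.0617, padj = 0.395) and PERP at 0.43 (SE 0.0785, padj = 0.395), and 5 without the H1299 p53 wild-type pair. There the average of G2/M genes fell, against the H1299 p53 wild-type pair (1 of 18 positive, median -0.32, padj = 2.83e-07), and p53 targets (23 of 24, median 0.22, padj = 3.85e-07, 4 adjusted over the list alone) and HIF targets (26 of 26, median 0.45, padj = 1.16e-05) rose. Their adjusted p with an estimated correlation was 0.489, 0.282 and 0.514.

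**Figure D2:**
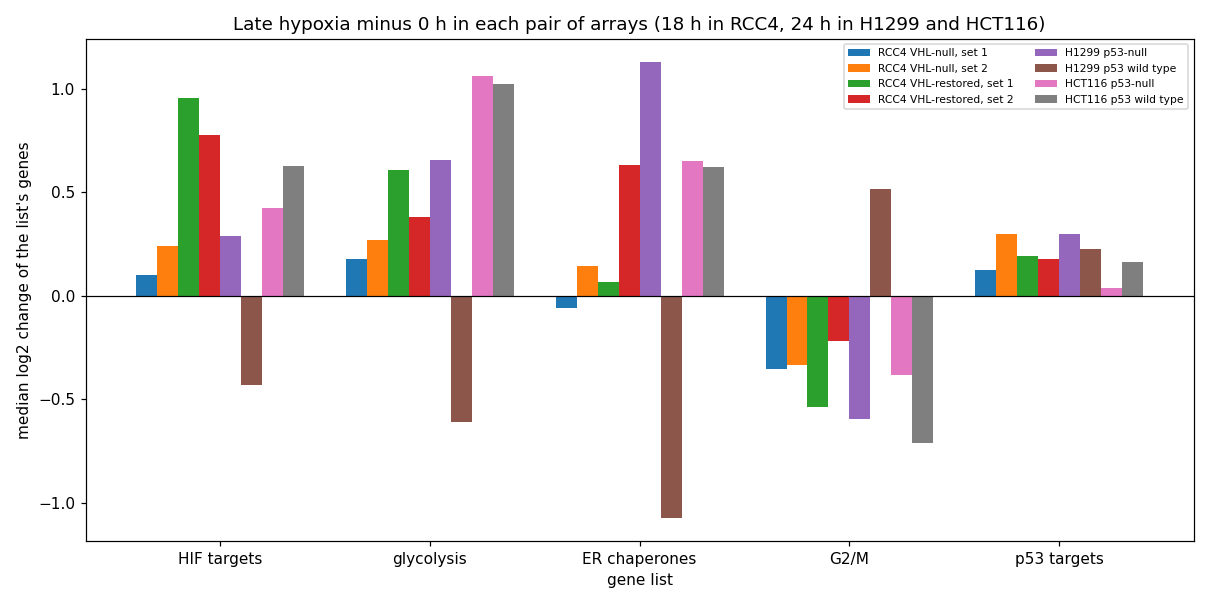
Median log2 change of the genes of 5 lists from 0 h to late hypoxia (18 h in RCC4, 24 h in H1299 and HCT116), 1 bar per pair of arrays, without error bars since each bar is a single pair. The bar of H1299 p53 wild type stands at -0.43 for HIF targets while the other pairs stand between 0.10 and 0.95.

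The comparison of p53 wild-type with p53-null cells at matched line and time asks what p53 alters (5 pairs of arrays). In HCT116 alone (3 pairs), MARCKS, an actin-binding kinase substrate, was 3.75-fold higher in wild-type cells (log2 1.91, SE 0.0678, limma adjusted p = 0.0102), and MACF1, a cytoskeletal linker, had a log2 difference of -1.20 (SE 0.0685, padj = 0.0499). Each kept its direction in the 3 pairs, and these were the 2 genes called (557 at an unadjusted p under 0.05). Known p53 targets had values that did not pass: FAS, a death receptor, 0.56 (SE 0.0650, padj = 0.179), GDF15 0.54 (SE 0.0702, padj = 0.190), FUCA1 0.35 (SE 0.0550, padj = 0.337), CDKN1A 0.34 (SE 0.113, padj = 0.578) and PERP -0.52 (SE 0.0668, padj = 0.190). MDM2 hardly differed, at 0.01 (SE 0.0692, padj = 0.981). DDB2 changed from 0 h by 1.30 at 12 h and 0.84 at 24 h in wild-type HCT116 and by -0.42 and -0.35 in p53-null HCT116, values of single arrays. Leaving out any of the 3 pairs left 0 genes.

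The list of p53 targets was higher in wild-type HCT116 (22 of 24, median 0.18, camera adjusted p = 7.21e-06, 0.415 with an estimated correlation), and adjusted over the list alone 8 members were higher and 2 lower. Endoplasmic reticulum chaperones (13 of 13, median 0.15, padj = 0.000102) and metallothioneins (6 of 6, median 0.17, padj = 0.00423) were higher too, each at 0.415 with an estimated correlation. In all 10 of 19 lists were called there, 7 up and 3 down, and 0 with an estimated correlation. The other 4 up were oxidative phosphorylation (median 0.09, padj = 0.00274), ATF4 genes (median 0.08, padj = 0.00906), HIF targets (median 0.07, padj = 0.0134) and interferon genes (median 0.04, padj = 0.0331). Down were G2/M genes (median -0.14, padj = 0.00906), lipid and cholesterol synthesis (median -0.09, padj = 0.0134) and heat shock genes (median -0.08, padj = 0.0286). By pair, G2/M genes stood at 0.07 (11 of 18 higher) at 0 h, -0.08 at 12 h and -0.40 at 24 h, so their value rests on 24 h. Over both lines limma called 0 genes (526 at an unadjusted p under 0.05, smallest adjusted p 0.0566), with CDKN1A at 0.34 (SE 0.0758, adjusted p = 0.721), FUCA1 at 0.24 (SE 0.0648, padj = 0.721) and SUSD6 at 0.19 (SE 0.0441, padj = 0.721). MDM2 stood at 0.03 there (SE 0.0533, padj = 0.935). The p53 target list was called (21 of 24, median 0.16, padj = 4.98e-05, 0.682 with an estimated correlation). In H1299 its median was only 0.09 at 0 h and 0.05 at 24 h, with 15 of 24 higher at each. In HCT116 it was 0.12 at 0 h, 0.27 at 12 h and 0.16 at 24 h, with 16, 19 and 20 of 24 higher, so the value rests mainly on HCT116. Without the H1299 arrays, 2 genes were called.

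The p53 by hypoxia interaction asks whether the hypoxic change depends on p53, with 2 residual degrees of freedom. Endoplasmic reticulum chaperones had a lower change with wild-type p53 (0 of 13 positive, median -1.06, camera adjusted p = 0.000257), as did ATF4 genes (3 of 19 positive, median -0.61, padj = 0.000257) and glycolysis (2 of 17 positive, median -0.48, padj = 0.00282), all at 0.769 with an estimated correlation. HIF targets were not called (median -0.28, padj = 0.105), and limma called 0 genes (811 at an unadjusted p under 0.05). By line, chaperones changed at 24 h by 1.13 in p53-null and -1.07 in wild-type H1299, and by 0.65 and 0.62 in HCT116. ATF4 genes changed by 0.59 and -0.55 in H1299 and by -0.17 and -0.22 in HCT116, and glycolysis by 0.66 and -0.61 in H1299 and by 1.06 and 1.02 in HCT116. In each list the genotypes lay farther apart in H1299 than in HCT116, and these are single arrays.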

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

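The tests of explanations given here were all chosen only after the results were seen.

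In H1299 p53 wild-type cells the HIF targets had a median change of -0.431 from 0 h to 24 h, below 0 while the other 3 backgrounds of H1299 and HCT116 stood above 0, and with a single pair of arrays this difference was not tested. Across genes, which are not independent replicates, the change of that pair correlated at -0.61 with the change in p53-null H1299. A reversal of the response by p53 in both lines is argued against by p53 wild-type HCT116, where the HIF median was 0.626 with 25 of 26 genes higher. The 0 h and 24 h labels of the pair may have been exchanged, or labels may have moved in a circle among 3 of the 4 H1299 arrays, in which cases the genotype difference at 0 h would correlate with that at 24 h at 0.243 or at -0.243 across genes, against -0.432 as labelled and 0.0508 in HCT116. Neither value decides: p53 targets would differ between the genotypes by medians of 0.451 and -0.206 at 0 h and 24 h after the exchange, and by 0.451 and 0.206 after the circle, against 0.0937 and 0.0491 as labelled, so with single arrays these cannot be told apart from each other or from a p53 effect in H1299 alone, which stays open and untested.

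The RCC4 arrays labelled 1 h and 4 h held 104 and 451 genes changed from 0 h, more than those labelled 2 h and 6 h with 2 and 0. A difference in scale between the array sets is argued against, since within set 2 alone 721 genes were called at 4 h. That fit does not cover differences among the arrays of set 2. Null entries made up 18.4% to 40.4% there, and the log2 gene medians before centring ran from 7.55 to 8.05. In set 1 these were 28.3% to 36.2% and 7.15 to 7.36. Whether this unevenness adds to the counts was not tested. An exposure as long as on the 18 h arrays may account for the larger counts at 1 h and 4 h. On the 1 h arrays p53 targets lay above those at 18 h in set 2, with 22 of 24 genes higher in each genotype. The median was 0.34 in VHL-null and 0.222 in VHL-restored cells, but the 18 h change itself differed between replicates by 0.265 and -0.0161. A response that is large by 1 h and 4 h predicts p53 targets raised at 2 h as well. Their median at 2 h in VHL-restored cells was -0.0415, so they were not raised there. That value comes from the other array set, so it cannot decide. The times 1 h and 4 h lie in set 2 and 2 h and 6 h in set 1, so no series within a set holds both, and the long exposure and the early response cannot be told apart.

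With the replicate number as a block, 43 genes had a VHL by hypoxia interaction by test, and the HIF targets had a median difference of -0.628. A difference between the array sets as the whole cause is argued against by set 2 alone, where the median was -0.504 with 23 of 26 members below 0, against -0.874 in set 1. A saturated signal in the VHL-null cells at 0 h is argued against as well. There 0 of 26 members came near the array's highest value (its midpoint was the limit), the brightest being IGFBP3 at 1884 against 4090 and 4330. The VHL-null arrays at 18 h were not examined, and neither was saturation of single probe sets at lower intensities, so these stay open. The interaction is by construction the genotype difference at 18 h minus that at 0 h. For HIF targets the median of VHL-null minus VHL-restored was 0.92 at 0 h and 0.01 at 18 h in set 1. In set 2 it was 0.48 and -0.11. The smaller change without VHL thus goes with a higher level at 0 h, not with a lower level of that size at 18 h. Whether targets already raised in oxygen have less left to rise was not tested and stays open.

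The VHL by hypoxia interaction also differed by camera test for 7 other lists, given as median differences. Glycolysis stood at -0.299, heat shock genes at 0.299, chaperones at -0.158 and ATF4 genes at -0.0905. Oxidative phosphorylation stood at 0.134, S phase genes at 0.117 and splicing genes at 0.166. The adjusted p of these 7 with an estimated correlation lay between 0.249 and 0.420.

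The p53 by hypoxia interaction differed by camera test for 3 lists, with median differences of -1.06 for chaperones, -0.61 for ATF4 genes and -0.485 for glycolysis, each at an adjusted p of 0.769 with an estimated correlation. In H1299 the p53-null and wild-type medians at 24 h were 1.13 and -1.07 for chaperones, 0.59 and -0.55 for ATF4 genes and 0.66 and -0.61 for glycolysis, against 0.65 and 0.62, -0.17 and -0.22, and 1.06 and 1.02 in HCT116. The differences thus rest on H1299 and its p53 wild-type pair, whose time labels are in doubt.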

How the results depend on the processing

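Chosen only after the results were seen were leaving out null entries, the array set as a block, fits within an array set, and leaving out arrays of H1299 or the arrays at 1 h and 4 h. For single genes named in the text, 2644 results kept their direction and side of the threshold, 185 lost and 131 gained a call, and 4 reversed. Unless stated, the cause of a changed count was not tested.

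Counts of genes called by limma follow. The replicate block raised VHL-null hypoxia from 0 to 37, VHL-restored hypoxia from 3 to 501, VHL at 0 h from 9 to 572, VHL at 18 h from 2 to 578 and the interaction from 0 to 43. In the fits of all 20 RCC4 arrays it gave 4381 (hypoxia 1 h vs 0 h in RCC4, shared by both VHL genotypes), 11 at 2 h, 4697 (hypoxia 4 h vs 0 h in RCC4, shared by both VHL genotypes), 4752 (reoxygenation 1 h vs hypoxia 18 h in RCC4, shared by both VHL genotypes) and 4500 (reoxygenation 4 h vs hypoxia 18 h in RCC4, shared by both VHL genotypes). In those fits the arrays of set 2 outside 0 h and 18 h are numbered 1, so this block mixes the sets with the times. The array set as a block gave 275 at 1 h, 11 at 2 h, 810 at 4 h and 200 at 4 h of oxygen. Without the arrays at 1 h and 4 h it gave 9 at 2 h and 174 at 4 h of oxygen. Set 2 alone gave 186 at 1 h and 721 at 4 h, and set 1 alone gave 4 at 2 h.

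Without centring the count was 0 for VHL-restored hypoxia, 2 and 0 for VHL at 0 h and 18 h, 0, 0 and 12 at 1 h, 2 h and 4 h, 4 at 4 h of oxygen and 1 for p53 in HCT116. Quantile normalisation gave 69 at 1 h and 1 for p53 in HCT116. No filter gave 1 for VHL-restored hypoxia and for VHL at 0 h and 18 h, 321, 0 and 822 at 1 h, 2 h and 4 h, 7 and 252 at 1 h and 4 h of oxygen, and 0 for p53 in HCT116. The upper 30% gave 3 and 0 for VHL at 0 h and 18 h, 19, 0 and 133 at 1 h, 2 h and 4 h, 6 at 4 h of oxygen and 1 for p53 in HCT116. A mean over probe sets gave 10 for VHL-restored hypoxia, 0 for VHL at 18 h, 246 and 0 at 1 h and 2 h, 140 at 4 h of oxygen and 0 for p53 in HCT116. A pseudocount of 64 gave 12 for VHL-restored hypoxia, 0 at 2 h and 1 for p53 in HCT116, and a pseudocount of 1 gave 1 for VHL at 18 h, 4 at 2 h and 0 for p53 in HCT116. Null entries left out gave 7 for VHL-restored hypoxia and 766 at 4 h, and a variance trend gave 1 for p53 in HCT116.

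Leaving out each RCC4 array in turn gave 0 to 6 genes for VHL-restored hypoxia, with 0 without VHL-restored 0 h replicate 1 or either 18 h replicate and 6 without either VHL-null 18 h replicate. VHL at 0 h had 1 to 8, with 1 without either VHL-null 0 h replicate or VHL-restored 0 h replicate 1 and 3 without VHL-restored 0 h replicate 2 or either VHL-restored 18 h replicate, and VHL at 18 h had 1 to 2, with 1 without any VHL-restored array or VHL-null 18 h replicate 2. The range was 38 to 148 at 1 h and 202 to 539 at 4 h, both lowest without VHL-restored 0 h replicate 1. It was 0 to 12 at 2 h, with 0 without VHL-restored 0 h replicate 1 or 2 or VHL-null 0 h replicate 2, 5 without VHL-restored 18 h replicate 2 and 12 without VHL-null 0 h replicate 1. It was 43 to 149 at 4 h of oxygen, highest without VHL-restored 18 h replicate 2. VHL-null hypoxia, the interaction, 6 h and 1 h of oxygen stayed at 0. Pairs left out gave 0 to 7 for 24 h hypoxia, with 7 without H1299 p53 wild type, 0 to 5 over 6 backgrounds, with 5 without that pair and 3 when set 1 alone was used as well, and 0 for p53 in HCT116. For p53 in both lines pairs left out gave 0, and leaving out H1299 gave 2.

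List calls numbered 110 with the preset correlation, 10 with an estimated correlation and 98 to 126 in the other settings. MDM2 in VHL-restored hypoxia ran from -0.0225 without VHL-restored 18 h replicate 1 to 0.352 without replicate 2. NDRG1 at 18 h turned to -0.0026 with the mean over probe sets, and ran from -0.161 without VHL-null 18 h replicate 1 to 0.241 without replicate 2, with -0.0523 without VHL-restored 18 h replicate 2. A group left with 1 array is assumed to vary like the others. The p53 by hypoxia interaction could not be fitted without either 0 h pair. Set 1 alone could not be fitted for 1 h, 4 h and reoxygenation, nor set 2 alone for 2 h and 6 h.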

Other observations

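The splits of the samples were tests chosen only after the results were seen.

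Values of HCT116 cells at 12 h of hypoxia, single arrays that enter the p53 comparisons but no comparison of hypoxia with 0 h, are given beside 24 h. Both changes of a genotype subtract the same single 0 h array, so they are alike in part by construction. ADM was higher than at 0 h by log2 3.27 in p53-null and 3.22 in p53 wild-type cells, ENO2, the enolase, by 2.56 and 2.45, and BNIP3, the mitophagy receptor, by 2.58 and 2.96, values without a test. At 24 h these were 3.13 and 3.24 for ADM, 2.54 and 2.69 for ENO2, and 2.80 and 3.08 for BNIP3. The median of glycolysis genes was 0.95 and 0.98, with 17 of 17 higher in each genotype, and that of HIF targets was 0.44 and 0.47, against 1.06 and 1.02, and 0.42 and 0.63, at 24 h. Endoplasmic reticulum chaperones had medians of 0.86 and 0.62, and G2/M genes of -0.38 and -0.43, against 0.65 and 0.62, and -0.39 and -0.71, at 24 h. DDB2, the DNA damage recognition gene, was higher in wild-type than in p53-null HCT116 by 0.47 at 0 h, 2.18 at 12 h and 1.66 at 24 h.

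In RCC4 at 0 h oxidative phosphorylation genes were lower without VHL (5 of 25 positive, median -0.15, camera adjusted p = 0.00914, 0.666 with an estimated correlation), with 3 lower in limma under the replicate block, and heat shock genes were lower too (2 of 12 positive, median -0.15, padj = 0.0365, 0.577 with an estimated correlation). At 18 h G2/M genes were higher without VHL (14 of 18, median 0.09, padj = 0.00076, 0.444 with an estimated correlation), with 6 higher under the block. Under hypoxia for 18 h in VHL-restored cells AMD1, an enzyme of polyamine synthesis, fell by log2 1.13 (SE 0.166, adjusted p = 0.000345 under the block, 1 without it), and SCD rose by 1.17 (SE 0.115, padj = 5.48e-06 under the block, 0.633 without it).

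Other splits of the same arrays were counted for comparisons with at least 3 samples per group. For 24 h hypoxia in H1299 and HCT116, the labelled split called 0 genes, so that 35 of 35 splits reach it by construction and nothing is said about chance. Of these splits 3 could not be fitted and are counted as 0. The highest other split called 79, which points to a structure of the samples: it exchanges the 0 h and 24 h arrays of H1299 p53 wild type, and it is among the 8 splits that part every pair. For late hypoxia over 6 backgrounds, 100 of 100 drawn from 462 splits reach the 0 of the labelled split by construction, 2 could not be fitted and are counted as 0, and the highest other, 22, makes that same exchange.

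For p53 in both lines, 100 of 100 drawn from 126 splits reach the 0 of the labelled split, again by construction, and the highest other called 5, exchanging p53-null H1299 at 0 h with p53 wild-type H1299 at 24 h, while the 16 that part every pair called 0. With that exchange the H1299 arrays of a time share a group, so the estimate comes from the HCT116 pairs as labelled. For p53 in HCT116 the 10 splits are too few for a share under 0.05, with 2 genes in the labelled split, 0 in the highest other and 1 split as high as the labelled split, itself.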
